A study of Caenorhabditis elegans with 6 samples.

How the data were processed

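Small RNA from 3 High and 3 Low cultures of gravid F2 worms was treated with phosphatase and polynucleotide kinase by the authors, starting from 1 µg of total RNA, built into TruSeq small RNA libraries with inserts of 18 to 36 bp, and sequenced as single 50-nt reads on an Illumina HiSeq instrument. cutadapt 1.7.1, Bowtie 1.1.1, featureCounts 1.4.6 and DESeq2 1.8.1 are named per the submitters' processing notes. Their settings, the genome build, the annotation, the definition of the 22G, 26G and 21U classes, the strand counted and the treatment of reads that map to more than one place are not given in the sources used here.

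The deposited tables hold, for each class, a signal per feature and library, which is a read count divided by a size factor. In each table the nonzero values of a library were whole multiples of 1 step (100% within 0.01 reads), and the step was the same in the 3 tables, so whole reads were recovered by dividing by it. Size factors ranged from 0.66 in Low replicate 1 to 1.31 in Low replicate 2. Each table lists 46761 features, of which 45484 (97.3%) matched a gene of Ensembl release 115 by name; biotype and chromosome come from that match.

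Features with a mean normalized count of at least 5 over the 6 libraries were tested with limma-trend (R 4.3.3, limma 3.58.1) on log2 of the normalized count plus 1, High minus Low, two-sided, with Benjamini-Hochberg adjustment within each class and a threshold of 0.05. Fold changes are on that scale. Reported errors are SD for group means and the SE of limma for log2 differences, with n = 3 per group. A feature with no read in a group was compared with a floor of 3 counts over the group. Depth ranged from 1380170 to 2685999 reads per library in the 22G class, from 18704 to 37706 in the 26G class and from 37630 to 59648 in the 21U class.

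The 20 gene lists were transgene part genes, chaperones and heat shock genes, Argonautes, small RNA machinery, nuclear RNAi, histone methylation, histones, sperm, oocyte, meiosis and germline, early embryo, intestine, muscle, neurons, cuticle and hypodermis, ERGO-1 26G targets, insulin and stress, silencing targets, ribosomal RNA and ribosomal proteins. They, the tests, the samples, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a class, with an estimated correlation and the fry test beside it. Class totals were compared by an exact permutation test over 20 assignments, two-sided, smallest p 0.1.

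By the rule, the named genes of a class are the 12 largest rises and the 12 largest falls among features past the threshold whose groups do not overlap, the transgene part genes, in each list up to 4 members past the threshold with the largest change and the 2 with the highest mean, and, where fewer than 10 features of a class pass, the 5 with the smallest p in each direction. The text gives values for part of the members chosen by level and for part of the features chosen by smallest p. frm-1, hil-2, hil-3, K02E2.6 and fbxb-97 in the 22G class and the transgene features fall outside the rule and were chosen after their values were seen.

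The alternatives were a replicate block, pseudocounts of 0.5 and 5, no filter and a minimum of 20, TMM scaling, equal totals per library, limma without trend, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, an adjusted p under 0.1, each library left out in turn, and, chosen after seeing the data, identical features merged and edgeR without Low replicate 1. The test was tested on simulated data with the feature means and size factors of each class. The spread of each feature was estimated by edgeR after TMM scaling. The higher 26G and 21U totals of Low replicate 1 were not simulated. Features were drawn independently, with 100 changed by 2-fold and 100 by 4-fold in the 22G class (9402 features) and the 21U class (592). In the 26G class (272) these were 30 and 30. limma-trend made 150 calls in the 22G class, 4% of them on unchanged features, 11 in the 26G class (9.1%) and 100 in the 21U class (2%). The real tables hold features with the same values as another, so these shares need not hold for them. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15. No library was left out of the comparisons reported.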

Results

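Small RNAs were sequenced from gravid adult Caenorhabditis elegans cultures of strain BCN1050, which carries a daf-21 promoter::mCherry::unc-54 3′ UTR reporter together with a functional unc-119 copy in an unc-119(ed3) mutant of the N2 background. The daf-21 gene encodes the chaperone Hsp90. High worms descended from P0 animals kept at 25 °C and Low worms from P0 animals kept at 16 °C. Both were moved to 20 °C as L4 larvae, 12 per plate, the F1 grew for about 4.5 days and was bleached, and the F2 grew from L1 larvae for 72 hours at 20 °C at 1000 per plate before RNA was extracted, so the sequenced worms themselves had grown at 20 °C. There were 3 High and 3 Low libraries, named biological replicates by the submitters, and each library gave a normalized read count per annotated feature for 3 small RNA classes. The 22G class is named after secondary small RNAs made by RNA-dependent RNA polymerases on target transcripts and loaded into worm-specific Argonautes, the 26G class after primary small RNAs loaded into ERGO-1 or ALG-3 and ALG-4, and the 21U class after the piRNAs bound by PRG-1. How the submitters defined each class from the reads, on which strand and with which genome build, is not given in the sources used here, so no coordinates are printed.

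The 22G class held most of the reads. The whole reads recovered for it were 1923919, 2334403 and 2508013 in High replicates 1 to 3, and 1380170, 2685999 and 1915854 in Low replicates 1 to 3. The 26G class held 18704, 19692 and 22670 reads in High and 37706, 23974 and 24339 in Low, and the 21U class held 37630, 48776 and 50846 in High and 39170, 59648 and 42976 in Low. A mean of at least 5 normalized counts, the minimum for a test, was reached by 9402 of the 17873 features with a 22G read, by 272 of 4119 with a 26G read and by 592 of 7634 with a 21U read. The floor of 3 counts used where a group had no read covers counting error only, and the p-values measure the spread between samples.

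The first comparison asks which 22G small RNAs differed between F2 worms whose grandparents had lived at high or at low temperature. 22G RNAs were higher in High over 10 of 25 tested cuticle genes and over 16 of 17 tested genes of histone H2A. They were also higher over the neuropeptide-processing gene egl-21. Signal of the 22G class was higher over 18S and 26S ribosomal RNA, where fragments of the rRNA cannot be told apart. A smaller set of genes was lower, including the pyruvate kinase gene pyk-1 and the sensory channel gene osm-9. unc-119 was lower too, where reads of the unc-119 copy of the transgene may have been counted. The FERM-domain gene frm-1, which carried the most 22G signal of all features in High, was at 45910 ± 146.1 normalized counts in High and 13930 ± 1035 in Low (SD, n = 3 each), a log2 difference of 1.72 ± 0.06 (SE, limma adjusted p = 1.62e-08). The gene was chosen after its values were seen. It took 2.21% ± 0.0285 of the 22G signal in High and 0.678% ± 0.0606 in Low (SD, n = 3).

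**Figure D1:**
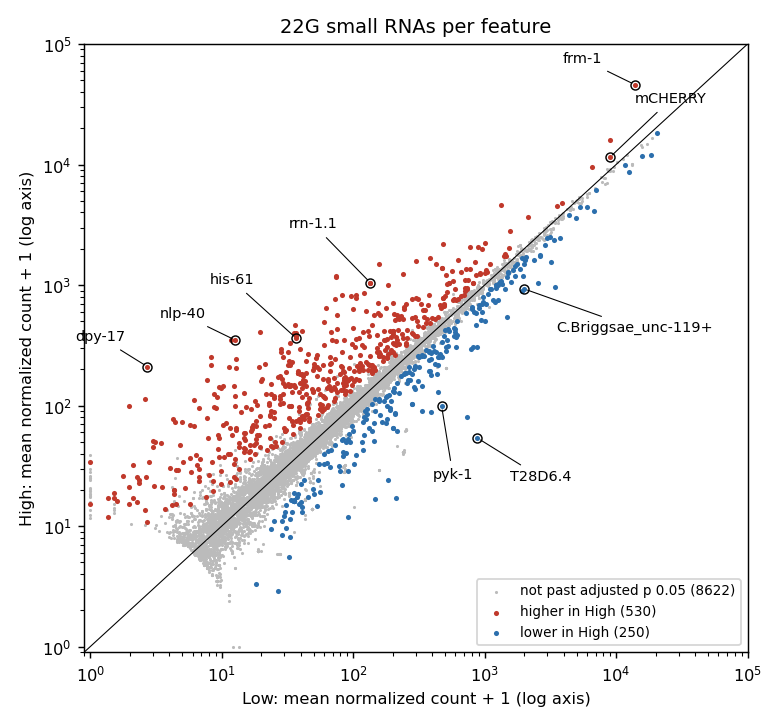
Mean 22G normalized count plus 1 of each of the 9402 tested features in Low (horizontal, log axis) and High (vertical, log axis), with the features past an adjusted p of 0.05 in red (530 higher in High) and blue (250 lower in High); rings mark features named in the text, and the line marks equality. Features higher in High reach far from the line at low Low counts, as for dpy-17 and nlp-40.

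Among the 9402 tested features, limma-trend called 780 at an adjusted p under 0.05, of which 530 were higher in High and 250 lower. The difference was over 2-fold for 349 of the higher and 89 of the lower features, and over 8-fold for 75 and 5. In each of the 780 the 3 High libraries lay apart from the 3 Low libraries, and of all tested features 2137 (22.7%) did so, where chance gives 10% for 3 against 3. The called features carried 21.73% of the 22G signal in High and 18.55% in Low. edgeR called 776 features, 766 of them shared, and DESeq2 called 703, 677 of them shared, whereas limma without a trend in the variance called 524. Of the tested features 473 had the same values as another, and counting each set once left 758 called features, 516 higher and 242 lower.

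Among the rises, the cuticle collagen gene dpy-17 had 209 ± 89.1 normalized counts in High and 1.72 ± 0.34 in Low, a log2 difference of 6.2 ± 0.31 (limma adjusted p = 3.13e-07). The neuropeptide gene nlp-40 had 348 ± 40.6 against 11.7 ± 6.49 (4.9 ± 0.29), and the cathepsin gene cpz-1 had 215 ± 63.4 against 7.24 ± 2.51 (4.72 ± 0.28). The features Y37E11AL.2, W02D3.12, R09A1.2, M02B7.7 and Y48G9A.7 rose by 5.80, 5.66, 5.06, 4.86 and 4.67 on the log2 scale. C42D4.19 had 33 ± 26.4 normalized counts in High and no read in any Low library, and was at least 32.1-fold higher against a floor of 3 counts over the Low group, or 20.7-fold without High replicate 3. The C-type lectin gene clec-104 had 49.1 ± 32.6 against 2.12 ± 3.67 (4.45 ± 0.78), with an adjusted p of 0.0031 by limma and one above 0.05 under 3 of 18 alternative settings, one of them without High replicate 3, up to 0.0685. C25D7.2 and C25D7.14 had nearly the same values (6.03 ± 1.28 and 6.02 ± 1.28), so which of them a read came from is uncertain. They varied widely between libraries (1178 ± 718 and 1171 ± 713 normalized counts in High, 72.64 ± 117 in Low for both). Without Low replicate 1 the log2 differences were 7.899 and 7.89. They lost their calls under 5 of 18 alternative settings, including without High replicate 2, High replicate 3 or Low replicate 3.

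Among the falls, T28D6.4 had 52.7 ± 5.89 normalized counts in High and 881 ± 7.55 in Low, a log2 difference of -4.04 ± 0.10 (SE, n = 3 each; limma adjusted p = 3.95e-09). The glycolytic gene pyk-1 had 97.3 ± 7.39 against 470 ± 42 (-2.26 ± 0.10), and tag-163 had 80.1 ± 24.9 against 727 ± 194 (-3.18 ± 0.22). The TRPV channel gene osm-9 fell by 2.98, the zinc finger gene fezf-1 by 2.55, the F-box gene fbxa-184 by 2.14 and the lipase-related gene lips-14 by 2.05 on the log2 scale. F08G5.3, ZC190.8 and F22B7.9 fell by 3.72, 3.24 and 2.93. ZC190.7 fell by 3.81, with a call that DESeq2 did not make (adjusted p = 0.0764). C15H11.11 fell by 2.48 from a low level, 17.3 ± 9.78 normalized counts in Low, and lost its call under 5 of 17 alternative settings, among them without High replicate 1, High replicate 2, Low replicate 2 or Low replicate 3.

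**Figure D2:**
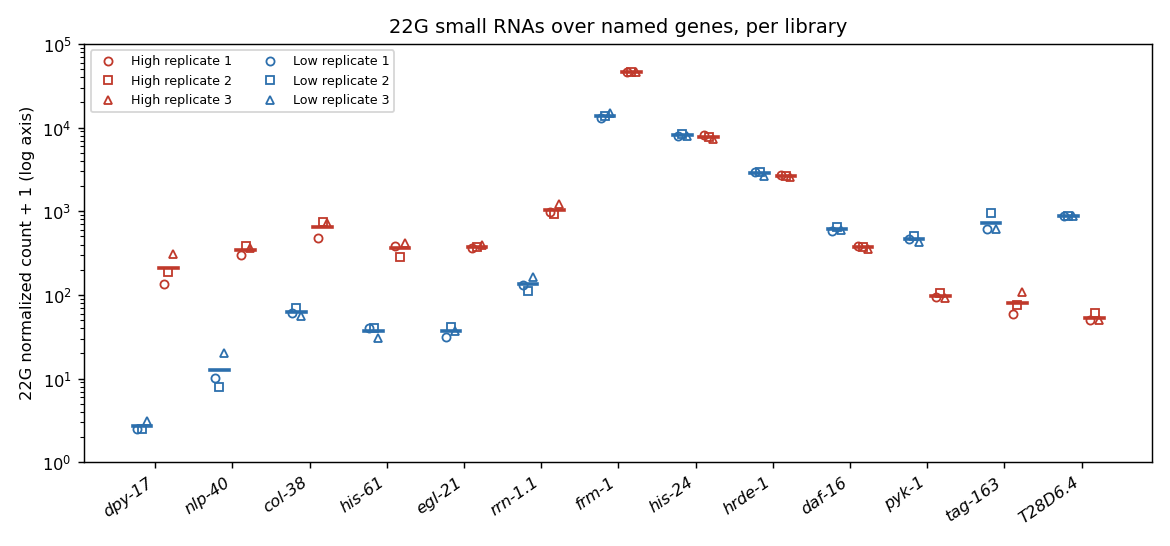
22G normalized count plus 1 (log axis) of 13 named genes in each library, as open symbols by replicate for Low (blue) and High (red), with the group mean as a bar. The symbols of High and Low are apart for the genes that passed the test and close together for his-24 and hrde-1.

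The cuticle genes showed the widest changes of the fixed lists. Of 96 genes in the cuticle and hypodermis list, 25 had enough 22G signal for a test, 10 of them were higher in High and 0 lower (10 and 0 also adjusted over the list alone). The collagen gene col-38 had 650 ± 150 normalized counts in High and 60.7 ± 6.62 in Low (3.38 ± 0.16), col-158 had 16.09 ± 5.14 against 0.35 ± 0.61 (3.70 ± 0.55), and col-7 had 18.9 ± 1.44 against 3.33 ± 2.65 (2.41 ± 0.50), the last with the same values as another feature and with a call lost without High replicate 2 or High replicate 3. The most abundant member, col-71, was at 2287 ± 84.9 and 2169 ± 153 and did not pass (limma adjusted p = 0.636). camera gave the list an adjusted p of 1.4e-05 with its preset correlation; with an estimated correlation the p was 0.0839 and the adjusted p 0.797. The median log2 difference of the list was 0.50.

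Among histone genes the rises of 22G signal in High lay mostly in H2A genes. Of 77 tested histone features, 18 were higher in High and 0 lower (18 and 0 adjusted over the list alone), or 12 of 61 when features with the same values are counted once. The H2A gene his-61 had 360 ± 70.4 normalized counts in High and 36.0 ± 5.52 in Low (3.28 ± 0.17, limma adjusted p = 3.81e-07). The H2A genes his-3, his-7 and his-19 rose by 2.69 ± 0.21, 2.66 ± 0.16 and 2.38 ± 0.25. H2A genes have near-identical sequences, his-19 is 1 of 4 features with the same values, and which copy a read came from is uncertain. Of the 18 higher features, 16 were H2A genes and the other 2 the linker histone genes hil-2 (0.67 ± 0.15) and hil-3 (0.42 ± 0.07), both chosen after their values were seen. Both calls were lost in limma without trend, and that of hil-2 also in DESeq2, in edgeR without Low replicate 1 and without High replicate 1, High replicate 2, High replicate 3 or Low replicate 3. The linker histone gene his-24, at 7764 ± 412 in High, did not pass (-0.06 ± 0.05, adjusted p = 0.647). camera gave the list an adjusted p of 1.82e-06; with an estimated correlation the p was 0.0561 and the adjusted p 0.797. The median log2 difference was 0.21 and the mean 0.50.

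Signal of the 22G class over the long ribosomal RNAs was higher in High. The strand counted is not given, so fragments of the rRNA itself cannot be told apart from 22G RNAs here. The 18S rRNA features rrn-1.1 and rrn-1.2, which share the same values, had 1046 ± 165 normalized counts in High and 134 ± 25.9 in Low (2.96 ± 0.14, limma adjusted p = 2.55e-07). The features rrn-3.1 and rrn-3.56, named after 26S rRNA, had 4641 ± 815 against 1334 ± 251 (1.8 ± 0.14) and 2072 ± 402 against 776 ± 122.1 (1.41 ± 0.14). The 5S rRNA feature rrn-4.2 had 10040 ± 904 against 13280 ± 5592 and did not pass (adjusted p = 0.494). Of 20 tested features of the rRNA list 4 were higher and 0 lower (4 and 0 adjusted over the list alone). By biotype 19 tested features were rRNA, of which 3 were higher, so not every member of the list is annotated as rRNA. The other 16 members had negative log2 differences, so the median was -0.47 and the mean 0.09. The direction by camera was upward with an adjusted p of 0.927. Without Low replicate 1 the list passed (adjusted p = 0.0145), and without Low replicate 2 its direction turned (adjusted p = 0.129).

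Of the neuronal list 13 genes were tested, 2 were higher and 1 lower (2 and 1 adjusted over the list alone). The carboxypeptidase gene egl-21, which acts in neuropeptide maturation, had 375 ± 14.1 normalized counts in High and 35.6 ± 5.1 in Low (3.37 ± 0.12, limma adjusted p = 3.71e-08). The cholecystokinin-like peptide gene nlp-12 rose by 1.76 ± 0.16. unc-119 fell by 1.07 ± 0.14, where reads of the unc-119 copy of the transgene may have been counted. camera gave the neuronal list an adjusted p of 0.411, while fry, which tests the genes of a set without comparing them with others, gave 0.00205.

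Of 20 tested targets of the ERGO-1 26G pathway 0 were higher in 22G signal in High and 5 lower (0 and 6 adjusted over the list alone). T08B6.2 had 49 ± 7.2 normalized counts in High and 86.8 ± 1.88 in Low (-0.82 ± 0.15), Y17D7C.3 had 1774 ± 118.8 against 2637 ± 218 (-0.57 ± 0.07), Y17D7B.4 had 1049 ± 39.7 against 1313 ± 74.5 (-0.32 ± 0.06) and W04B5.2 had 653 ± 40.8 against 806 ± 49.9 (-0.30 ± 0.07, limma adjusted p = 0.0267). K02E2.6, chosen after its values were seen, had 1259 ± 94.5 against 1506 ± 45.4 (-0.26, adjusted p = 0.0342). E01G4.5, at 2733 ± 158.1 and 3187 ± 262, passed when adjusted over the list alone (0.0335) and not over all features (0.101). camera gave the list an adjusted p of 0.0267; with an estimated correlation the p was 0.196 and the adjusted p 0.929, and the call was lost without High replicate 3 (0.202) and without Low replicate 2 (0.0507). The calls of W04B5.2 and K02E2.6 were each lost under 6 of 18 alternative settings (with replicates as blocks, in limma without trend and without High replicate 2, High replicate 3, Low replicate 2 or Low replicate 3), and that of Y17D7B.4 in limma without trend and without High replicate 2.

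22G RNAs over the genes of small RNA and chromatin pathways gave few calls. Of 16 tested Argonaute genes 0 were called and of 15 nuclear RNAi genes 0 were called by limma, and also 0 and 0 adjusted over each list alone. The germline nuclear Argonaute gene hrde-1 was at 2665 ± 74.9 in High and 2837 ± 180.7 in Low (adjusted p = 0.546), wago-4 at 1322 ± 75 and 1154 ± 111.7 (0.203), and nrde-2 at 952 ± 36.4 and 878 ± 27.9 (0.386). Of 54 tested members of the small RNA pathway list, which shares genes with the nuclear RNAi list, 1 was higher and 0 lower (1 and 0 adjusted over the list alone), the piRNA transcription gene prde-1 (0.67 ± 0.12), while eri-6 was at 5759 ± 295 and 6165 ± 188 (0.413). Of 40 histone methylation and deacetylation genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone). These were the H3K4 methyltransferase gene set-16 (1363 ± 52.8 against 770 ± 84.3, 0.83 ± 0.08, limma adjusted p = 3.87e-05) and the deacetylase gene hda-3 (-0.51 ± 0.09, a call lost in limma without trend), and set-9 was at 2698 ± 49.4 and 2583 ± 209 (0.706). The camera adjusted p was 0.988 for the Argonautes, 0.927 for nuclear RNAi, 0.875 for the small RNA pathway and 0.875 for histone methylation.

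Stress and signalling genes gave single calls. Of 22 insulin and stress pathway genes 1 was higher and 1 lower (2 and 1 adjusted over the list alone, the second rise being sod-4, 594 ± 14.7 against 494.5 ± 39.8). The FOXO factor gene daf-16 had 369 ± 19.2 normalized counts in High and 608 ± 37.3 in Low (-0.72 ± 0.08, limma adjusted p = 8.27e-05), the TFEB factor gene hlh-30 rose by 0.91 ± 0.15, and the insulin receptor gene daf-2 was at 599 ± 37.8 and 655 ± 2.14 (0.377). Of 37 chaperone and heat shock genes 0 were called by limma over all features and 0 adjusted over the list alone; hsp-60 was at 881 ± 38.1 and 742 ± 109.4 (0.175). The camera adjusted p was 0.927 for the insulin and stress list and 0.988 for the chaperones.

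Germline and tissue lists also held few calls. Of 43 oocyte genes the cyclin gene cyb-3 was called (220 ± 38.4 against 128 ± 33.9, 0.80 ± 0.18, limma adjusted p = 0.0189), 0 were called adjusted over the list alone, and egg-5 was at 1023 ± 26 and 1085 ± 30.8 (0.556). The call of cyb-3 was lost in limma without trend and without Low replicate 1, Low replicate 2, High replicate 2 or High replicate 3. Of 40 meiosis and germline genes the sex determination gene xol-1 fell by 0.43 ± 0.09 (adjusted p = 0.0138, 1 lower adjusted over the list alone). This call was lost in limma without trend and without High replicate 2, High replicate 3 or Low replicate 2. Of 9 sperm, 9 intestinal and 8 early embryonic genes tested, 0, 0 and 0 were called by limma and also 0, 0 and 0 adjusted over each list alone; cpb-1 was at 178.1 ± 11.9 and 195 ± 8.09 and the vitellogenin gene vit-5 at 21 ± 1.90 and 28.6 ± 4.1. Of 15 muscle genes unc-54 was called (1 higher adjusted over the list alone). Of 6 genes silenced by nuclear or piRNA-directed small RNAs, C38D9.2 rose by 0.44 ± 0.07, a call lost in limma without trend, and xol-1 fell (1 higher and 3 lower adjusted over the list alone, the 3 being xol-1, F37D6.3 and fbxb-97, the last chosen after its values were seen), while F37D6.3 was at 13980 ± 726 and 15690 ± 1078 (0.173) and bath-45 at 5704 ± 205 and 5981 ± 157 (0.584). Of 77 ribosomal protein genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone), rpl-11.2 by 1.87 ± 0.26, rla-1 by 0.71 ± 0.17 and rpl-38 by 0.68 ± 0.14. rla-1 lost its call in limma without trend, in DESeq2, in edgeR without Low replicate 1 and without High replicate 1, 2 or 3 or Low replicate 1 or 3. rpl-38 lost it in limma without trend and without High replicate 1 or 2 or Low replicate 2. The camera adjusted p was 0.927 for the oocyte list, 0.927 for meiosis, 0.988 for sperm, 0.618 for intestine, 0.875 for early embryo, 0.988 for muscle, 0.821 for the silenced targets and 0.927 for ribosomal proteins.

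Of the 19 lists tested in the 22G class 3 passed with the preset correlation of camera and 0 with an estimated correlation. fry called 3 lists, 2 of them shared. Without Low replicate 1, 4 passed. With 3 against 3 libraries an exact permutation test of any single value cannot give a two-sided p below 0.1. In simulated tables of the same size, limma-trend found 59% of 100 features changed by 2-fold and 85% of 100 changed by 4-fold in the 22G class.

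The second comparison concerns the reporter: whether 22G RNAs over the genes that lent their parts to the transgene differed between High and Low. They went different ways. unc-54, the muscle myosin gene whose 3′ UTR ends the reporter, was at 4486 ± 181.6 normalized counts in High and 3522 ± 128 in Low (0.35 ± 0.05, limma adjusted p = 0.0014). unc-119, the gene that the transgene restores, was at 91.1 ± 17.9 and 190 ± 12.33 (-1.07 ± 0.14, adjusted p = 0.000402). daf-21, whose promoter drives the reporter, was at 3354 ± 78.5 and 3167 ± 163.1 and did not pass (0.08 ± 0.06, adjusted p = 0.529). Adjusted over the list alone, 1 was higher and 1 lower as well.

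The tables also list parts of the transgene itself, which were chosen after their names and values were seen. The mCherry feature had 11450 ± 624 normalized counts in High and 8942 ± 731 in Low (0.36 ± 0.07, limma adjusted p = 0.0046), and the unc-54 3′ UTR feature had 4785 ± 212 against 3841 ± 140 (0.32 ± 0.06, adjusted p = 0.003). The daf-21 promoter feature, at 3822 ± 97.2 and 3669 ± 168.8, did not pass (adjusted p = 0.675). The Caenorhabditis briggsae unc-119 feature had 928 ± 95.7 normalized counts in High and 1994 ± 30.6 in Low (-1.11 ± 0.07, adjusted p = 2.74e-06), and a second feature for the same gene fell by 1.12. The ampicillin resistance feature fell by 0.49 (adjusted p = 0.0172), a call lost under 6 of 18 alternative settings, including without High replicate 2, High replicate 3, Low replicate 2 or Low replicate 3. The ColE1 origin (-0.10 ± 0.13) and the right and left ttTi5605 recombination features (-0.19 ± 0.11 and 0.05 ± 0.15) did not pass (adjusted p = 0.805, 0.429 and 0.918). The calls of mCherry, the 3′ UTR feature and unc-54 were lost when limma was run without a variance trend, with adjusted p-values of 0.165, 0.157 and 0.119. The daf-21 promoter, unc-54 3′ UTR and ttTi5605 recombination features hold sequence of the worm's own genome. The C. briggsae unc-119 features may share sequence with the worm's unc-119. Whether a read was counted at both places is not given in the sources used here.

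**Figure D3:**
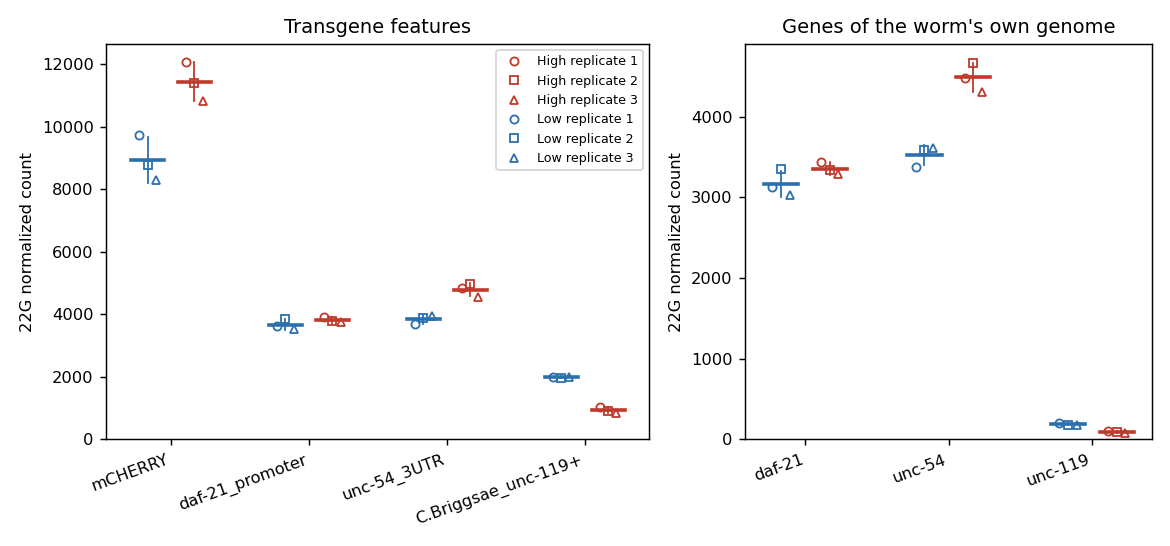
22G normalized count (linear axes from 0, of different height) of 4 transgene features (left) and of the worm's own daf-21, unc-54 and unc-119 (right), with each library as an open symbol by replicate, the group mean as a bar and the SD as a vertical line, Low in blue and High in red. mCherry, the unc-54 3′ UTR and unc-54 lie higher in High, and both unc-119 features lie lower.

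The third comparison asks the same of the 26G class. Signal over ERGO-1 targets, ribosomal RNA and other features did not pass the test between High and Low. Among 272 tested features limma called 0, with 3 at an unadjusted p under 0.05, and edgeR called 0. DESeq2, which gave an adjusted p to only 71 of these features, called 11, of which 1 was higher and 10 lower. frm-1 had 13.4 ± 11.56 normalized counts in High and 0.607 ± 0.546 in Low (unadjusted p = 0.0417, limma adjusted p = 0.518), F31E9.11 had 5.66 ± 2.08 against 13.4 ± 3.04, C16B8.8 had 2.91 ± 3.72 against 40.1 ± 54.7, and F02D10.14 had 162.9 ± 4.72 against 791 ± 888; these did not pass. Low replicate 1 stood apart in this class, with 2.59 times the signal of the mean of the other Low libraries. Without it limma called 1 feature and edgeR 8, among them frm-1.

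The 17 tested ERGO-1 targets in the 26G class had 0 called features, also adjusted over the list alone, and the most abundant, Y17D7C.3, was at 579 ± 58.1 normalized counts in High and 725 ± 91.5 in Low (-0.32 ± 0.27, limma adjusted p = 0.618), a difference whose sign turned under TMM scaling, under equal library totals, in edgeR and in DESeq2. The list's median was -0.33 and its mean -0.26, against a median of -0.53 over all tested 26G features, which moved to 0.03 under TMM, and camera gave an upward direction with an adjusted p of 0.354 (0.745 with an estimated correlation). The list passed under TMM (0.000887), with a minimum of 20 normalized counts (0.0323) and without Low replicate 3 (0.0441), and its direction turned without High replicate 1 or Low replicate 1. In simulated tables limma found 10% of 30 features changed by 2-fold and 23.3% of 30 changed by 4-fold. Of the latter edgeR found 43.3% and DESeq2 46.7%. The simulated features were independent, whereas 123 of the 272 real ones had the same values as another. The excess of Low replicate 1 in this class was not simulated. The adjustment is also more lenient where many features change, so these shares need not hold for the real class.

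The fourth comparison concerns the 21U class. The protein-coding feature frm-1 passed the test, with 107.1 ± 37.1 normalized counts in High and 15.7 ± 4.81 in Low (2.68 ± 0.35, limma adjusted p = 0.0086). Of the 38 tested features annotated as piRNAs 0 were called. Among 592 tested features 1 was higher and 0 lower, and edgeR called 2 and DESeq2 1. The groups did not overlap in 31.1% of features. The 10% that chance gives is no reference here, as the class as a whole was shifted down with the deposited size factors. In addition, 196 features had the same values as another. The call of frm-1 was lost with replicates as blocks and without High replicate 2, High replicate 3 or Low replicate 3 (adjusted p up to 0.118), and without Low replicate 1 there were 33 calls, 5 higher and 28 lower, and without Low replicate 2 there were 20, 2 higher and 18 lower. At an adjusted p under 0.1 there were 23 features, 3 higher and 20 lower, of which 14 had one set of values. These lower features were found with the deposited size factors, with which the median log2 difference of the class was -0.384; under TMM it was -0.017 with 3 called features higher and 0 lower, edgeR called 2 higher and 0 lower, and edgeR without Low replicate 1 called 11 higher and 0 lower. The features at an adjusted p under 0.1 included B0285.12 (9.81 ± 0.88 against 30.5 ± 5.12), rrn-3.1 (23.9 ± 3.16 against 8.60 ± 2.28), Y46G5A.43 (15.4 ± 3.68 against 5.22 ± 1.44) and B0284.1 (19.6 ± 3.09 against 57.6 ± 27.6), each with a limma adjusted p of 0.0786; F59C12.4 and F59A7.7 had 0.105 and 0.121. B0284.1 has the same values as another feature.

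Ribosomal RNA was the list that passed in this class. Of 7 tested features of the rRNA list 0 were called over all features and 1 was higher adjusted over the list alone. The median log2 difference was 0.61 and the mean 0.31 against a class median of -0.38, and camera gave an adjusted p of 0.027. With an estimated correlation the p was 0.215 and the adjusted p 0.563, and the call was lost in fry, with replicates as blocks, under TMM, with identical features merged and without High replicate 1 or Low replicate 2. Argonaute genes had 5 tested members, histone methylation genes 5 and ERGO-1 targets 7, with 0, 0 and 0 called by limma, also adjusted over each list alone, and camera adjusted p-values of 0.706, 0.166 and 0.809; the Argonaute gene csr-1 was at 4.2 ± 1.33 and 9.41 ± 2.39 (adjusted p = 0.192). In simulated tables limma found 16% of 100 features changed by 2-fold and 82% of 100 changed by 4-fold. The simulated features were independent, whereas 196 of the 592 real ones had the same values as another. The higher total of Low replicate 1 in this class was not simulated. With so many changed features the adjustment is also more lenient, so these shares need not hold for the real class.

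The last comparison sets the class totals side by side. The 22G total was 2081000 ± 33560 normalized counts in High and 2057000 ± 32230 in Low, a ratio of 1.01 (exact permutation p = 0.4, n = 3 each). The 26G total was 18880 ± 1577 against 33740 ± 20610, a ratio of 0.56 (exact permutation p = 0.3) that was 0.857 without Low replicate 1, and the 21U total was 42120 ± 1045 against 50140 ± 7987, a ratio of 0.84 (exact permutation p = 0.1, the smallest p of this two-sided test). The size factors are shared by the 3 tables and follow the 22G reads. The 22G ratio lies near 1 by the scaling and is no measure of the 22G level, and the 26G and 21U ratios are relative to the 22G class.

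**Figure D4:**
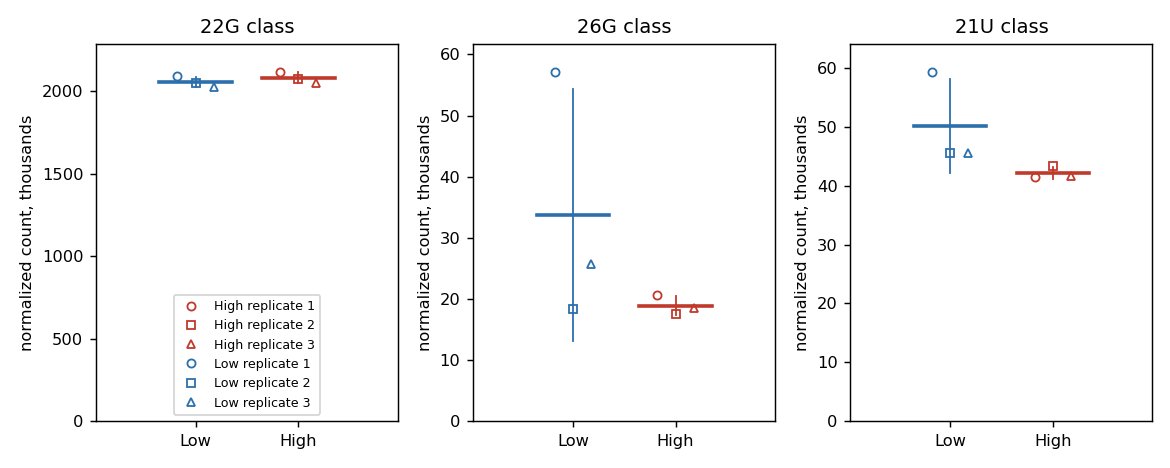
Sum of the normalized counts (in units of 1000, linear axes from 0) of each library in the 22G, 26G and 21U class, with libraries as open symbols by replicate, the group mean as a bar and the SD as a vertical line. In the 26G class Low replicate 1 lies far above the other 5 libraries.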

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

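The merging of identical features and edgeR without Low replicate 1 were chosen after seeing the data. Of the 65 called features named in the text, 43 kept their call under each of up to 18 alternative settings and 22 lost it under at least one, with 0 changes of direction; limma without trend ended 19 calls, leaving out High replicate 2 ended 14 and High replicate 3 12. In the 22G class the count of called features ranged from 524 (limma without trend) to 897 (no filter) at the same threshold, and from 563 to 752 with one library left out; the 2 called transgene part genes were called under each of the 15 settings run for their count, with unc-54 lost in limma without trend, and the class total kept its ratio within 1 SD. With the replicate number as a block there were 782, 0 and 0 called features in the 22G, 26G and 21U classes; same-number libraries did not correlate above 0.05 in the 22G class. The 22G lists passing numbered 0 with an estimated correlation and 2 to 4 with one library left out, and the ribosomal RNA list turned without Low replicate 2 (adjusted p = 0.129; range with one library left out 0.0145 to 0.975). In the 26G class called features numbered 11 by DESeq2 (1 higher, 10 lower), among the 71 features to which it gave an adjusted p. They numbered 8 by edgeR without Low replicate 1 (2 and 6), and 0 to 1 with one library left out. The 26G lists passing numbered 1 under TMM, 1 with a minimum of 20, and 0 to 1 with one library left out. The ERGO-1 target list in that class turned in camera without High replicate 1 (0.981) and without Low replicate 1 (0.914), with a range of 0.0441 to 0.981 with one library left out. fry gave a downward direction (0.246) because it tests the list's own change, and 14 of its 17 log2 differences were negative. camera compares the list with the other features, so the 2 directions answer different questions. Y17D7C.3 in that class turned to 0.28 under TMM, 0.35 with equal totals, 0.23 in edgeR and 0.23 in DESeq2. In the 21U class called features numbered 0 with a block, 28 with no filter (6 higher, 22 lower), 2 with a minimum of 20 (1 and 1), 3 under TMM (3 and 0), 2 in edgeR (2 and 0), 2 with identical features merged (1 and 1), 11 in edgeR without Low replicate 1 (11 and 0), 23 at an adjusted p under 0.1 (3 and 20), and 0 to 33 with one library left out (5 and 28 at the highest); no feature was called lower under TMM or in edgeR. The 21U lists numbered 0 with an estimated correlation, in fry, with a block, under TMM and with identical features merged, and 0 to 1 with one library left out; a minimum of 20 left too few members for a value. TMM, edgeR and DESeq2 take their scaling from the reads of each class in place of the deposited size factors. In that order, the 26G median log2 difference moved from -0.527 to 0.028, -0.009 and -0.012. The 21U median moved from -0.384 to -0.017, -0.026 and -0.016. Under TMM only the scaling changed, so the turn of Y17D7C.3 and the absence of lower 21U calls there follow from it. For the other changes the cause was not tested, except that fewer libraries or features enter where they are left out. The 26G class had 18704 to 37706 reads per library, and no setting varied the depth.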

Other observations

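The tests of the biotypes, the chromosomes, the H2A genes, the transgene parts and the 21ur loci were chosen after the result was seen. So were those of the 21U and 22G classes at the same features and of the splits. The tests of the size factor, near-copies and batch of Low replicate 1 were also chosen after the result was seen. The test of identical features in Low replicate 1 was not.

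Pseudogenes made up 499 of the tested 22G features and carried 13.77% of the 22G signal. Of these, 25 (5.01%) were higher in High and 40 (8.02%) lower, against 2.36% lower among the other tested features (Fisher's exact test, two-sided, p = 2.54e-10). The comparison treats features as independent and did not match them by level. The lower pseudogenes include the ERGO-1 targets T08B6.2, Y17D7C.3 and W04B5.2. Small nuclear RNA features numbered 91, of which 0 were called by limma in either direction, and 7 of 59 small nucleolar RNA features were higher and 0 lower. In the 21U class a single non-coding feature, ZK930.13, took between 22.45% and 37.69% of the signal of a library, and features annotated as piRNAs took 8.99%. frm-1 stood out in more than one class: its 21U signal was 0.233% ± 0.0815 of its 22G signal in High and 0.115% ± 0.0421 in Low (SD, n = 3).

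Genes on the X chromosome had more falls and fewer rises of 22G signal than autosomal genes. Of 864 tested X features 61 (7.06%) were lower in High and 13 (1.5%) higher, against 170 (2.06%) and 504 (6.12%) of 8235 autosomal features, and the median log2 difference on X was -0.12. Within 5 bins of level the odds ratio of a fall on X was 4.78 (Mantel-Haenszel, 95% confidence interval 3.49 to 6.55). The excess stood at 61 and 13 under TMM, 66 and 13 with equal totals, and 52 and 14 without Low replicate 1. camera gave X a p of 1.17e-05 with its preset correlation and 0.07 with an estimated one. A lower 22G level over X-linked genes in High may be a shift of the chromosome as a whole, but genes of a chromosome are not independent and the test with an estimated correlation leaves this open.

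The 22G signal over H2A genes was higher in High at 16 of 17 tested H2A features (10 of 11 with features of the same values counted once) and at 0 of 48 features of the other core histones. A larger amount of core histone transcripts or of their fragments would raise H2A, H2B, H3 and H4 together; the median log2 difference of the others was 0.126 (median absolute deviation 0.32) against 1.58 (1.18) for H2A, which argues against it. One set of reads counted at every H2A copy would give each the same gain; his-61 gained 323 ± 40.8 normalized counts and his-16 66.2 ± 16 (SE), a difference of 257 ± 32.7, which argues against a single set. As H2A was compared with the other core histones only, a larger amount of H2A transcripts or fragments alone stays open. The strand counted is not given. It also stays open that a few H2A copies carry the signal and lend reads to the others. So does a difference of 22G RNAs against H2A transcripts with the temperature of the grandparents. None of these was tested further.

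Low replicate 1 had the most 26G and 21U signal of the 6 libraries, and its excess in the 26G class lay in non-coding RNA features, at 4.04 times the mean of the other Low libraries against 1.23 times for genes, pseudogenes and lincRNAs. Its small size factor is argued against for the 26G class, where its reads before scaling were 1.55 times those of the highest other library, and stays open for the 21U class, where they were 0.911 times those of the lower of the other Low libraries. One structural RNA counted at many identical features stays open: the merged total was 39330 against 21590 in the next library, a ratio of 1.82, but 59 tested features left after the merge lay within 2 reads or 2% of another in every library, so the merge did not count the copies of one RNA once. The number in this library's column name lies outside the run of the others, which holds for 1 library, so a separate library batch cannot be told apart from this culture. No biological explanation was tested.

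The transgene parts differed in their 22G change: mCherry and the unc-54 3′ UTR were higher in High and C. briggsae unc-119 was lower. Reads shared by the unc-54 gene and the unc-54 3′ UTR of the transgene may account for the rise of unc-54, as the feature gained 963 normalized counts and the 3′ UTR 945, and their difference changed by -18.7 ± 37.3 between Low and High. Reads shared by unc-119 and the C. briggsae unc-119 feature may likewise account for the fall of unc-119. Their log2 differences were -1.07 ± 0.14 and -1.11 ± 0.07, and this sharing was not tested. A separate response of each part to the temperature of the grandparents stays open and was not tested.

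The total at 21ur loci, the annotated piRNA genes, was 3884 ± 226 normalized counts in High and 4413 ± 458 in Low (SD, n = 3), a ratio of 0.88 (exact permutation p = 0.2, smallest p 0.1). Of 275 such features with a read 38 were tested. The groups overlapped, as High replicate 3 (4118) lay above Low replicate 1 (3892). A lower 21U-RNA level in High was therefore not shown, and with 3 against 3 libraries the test could not have decided it.

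At features with a 22G call the 21U class may follow the 22G class. Of the 468 features tested in both classes 53 had a 22G call. Of these, 36 departed from the 21U median in the direction of their 22G change. The median of 100000 permutations was 26.5 (permutation p = 0.0061). The log2 differences of the classes correlated across these features (Pearson r = 0.74, Spearman rho = 0.68), which are not independent replicates. Features with the same values were not merged. The transgene features mCherry and unc-54 3′ UTR were counted beside unc-54, and the permutation p treats each as separate.

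The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each of the other splits both groups hold High and Low libraries. A difference between High and Low then widens the spread within the groups and lowers the number of calls. The counts of the other splits are therefore no measure of chance. The real split gave 780 called features in the 22G class and the highest other split 0, with 1 split at least as large; in the 26G class these were 0 and 0 (10 splits), and in the 21U class 1 and 0 (1 split). For gene lists the real split gave 3 and the highest other 3 in the 22G class (3 splits), 0 and 1 in the 26G class (10 splits), and 1 and 1 in the 21U class (5 splits).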
